A study of Arabidopsis thaliana with 12 samples.

How the data were processed

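RNA-seq was carried out on whole Arabidopsis thaliana seedlings aged 10 days, per the labels. There were 12 libraries in 4 groups of 3: wild type Col-0 and the mutant atrx-2, each grown in long days under normal light (130 µmol) or low light (30 µmol). The labels state the same temperature for both light levels, total RNA as input, a NEBNext Ultra II kit, single reads of 50 bases and a shared flow cell. They number the replicates but do not say that these came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

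The authors deposited 1 table of estimated counts per library, made with kallisto 0.42 against TAIR10 according to the submitters' processing notes, which also name DESeq2. Strand use, fragment length and index options are not given in the sources used here. The deposited tables also hold TPM values and effective lengths from the same program; the TPM values were not used. Each table lists 33602 transcripts, 1 per gene, so values describe genes and not isoforms. Between 12.3% and 13.9% of the deposited estimated counts were not whole (tolerance 1e-06), since kallisto divides ambiguous reads among transcripts. They were rounded to whole numbers before testing. Effective lengths were identical in all libraries, so an alternative with length offsets was void and was not run.

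Totals ran from 13733302 to 23899191 estimated counts per library. No pair of replicates agreed within sampling noise: the chi-square of their counts lay between 6.04 and 29.4 per gene, so all 12 libraries were kept as separate samples. Gene names, biotypes and coordinates came from the TAIR10.1 reference annotation, which held 32835 of the 33602 loci. Coordinates are 1-based.

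Counts were analysed with edgeR 4.0.16 under R 4.3.3. Genes were filtered with filterByExpr by group, which left 20783. TMM factors scaled the libraries, and the quasi-likelihood F test was fitted to the 4 groups together, with 8 residual degrees of freedom. The biological coefficient of variation was 10.4%. Contrasts gave the genotype effect at each light level, its average, the light effect in each genotype and the genotype by light interaction. Benjamini-Hochberg adjustment was applied over all tested genes within each contrast, and genes with an adjusted p under 0.05 are said to have risen or fallen. All tests were two-sided. CPM values were computed from TMM-scaled library sizes and are given as mean ± SD. Fold changes of genes with 3 or fewer counts in a group were replaced by a lower bound against a floor of 3 counts over the group, or by the ratio of pooled counts with an exact 95% Clopper-Pearson counting interval. Those intervals and bounds cover counting error only.

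The comparisons, the named-gene rule, 22 gene lists with 412 members and most alternatives were fixed before the data were examined. ATRX, FLC, the other FLC-clade genes, FT and LHP1 are always given. For each genotype and light comparison the rule took the 5 largest rises and the 5 largest falls among genes past the threshold with at least 1 CPM in the higher group and no overlap between replicate values. It also took up to 4 called members of each list, and for the interaction the genes with the smallest p. Other genes that are named were chosen after their values were seen: AT4G33110, AT2G40520, AT2G32870, PGL1, AT3G44120, AT3G61030, AT3G60930, AT5G28335, AT3G30122, AT2G15810, AT5G07570, GRP20, MYB29, MAM1, CYP79F1, SARD1, CCS, AT1G14730, AT2G32150, AT2G32160 and further members of the iron list. The seed storage list had 13 members and none was tested, as none passed the filter.

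Lists were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01, and again with an estimated correlation, Benjamini-Hochberg adjusted over the 21 tested lists of each comparison. The fry test was an alternative. Over the 126 list tests, 33 passed with the preset correlation and none with an estimated correlation, so no list call below holds under the latter. The fixed plan dropped members whose symbol and locus disagreed in the annotation. This was read as dropping only a symbol given to another locus, which removed 0 members, a reading settled after a first fit had been seen. The stricter reading, without 17 members whose symbol the annotation lacks, gave 32 list calls.

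The edgeR steps were tested on simulated counts for 20651 genes. In the genotype comparisons, 2-fold changes were recovered at 78% under normal light, 85.5% under low light and 96% averaged, and 1.5-fold changes at 47%, 50% and 73%. In the light comparisons the recovery was 81% in wild type and 90% in atrx-2 for 2-fold changes, and 59% and 59.5% for 1.5-fold changes. For the interaction it was 71% and 22%. Changes were planted only in genes of at least 1 CPM. Per fold size 200 genes were planted for genotype under low light and for light in atrx-2, and 100 in each other comparison. More planted genes loosen the adjusted threshold, so the recoveries do not rank the comparisons. The simulated genotype comparisons made 133, 281 and 282 calls and the interaction 100, against 14, 15, 64 and 1 in the data. Of the simulated calls 6.02%, 3.56%, 5.32% and 7% were false. Fewer calls make the adjusted threshold stricter, so the recovery given may overstate that in the genotype and interaction tests of the data.

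Alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE scaling, no low-count filter, a filter of 5 CPM, fits of only the 6 libraries compared, the replicate number as a block, an added log2 threshold of 1, libraries without organelle genes, and each library left out in turn. A covariate for the share of the 18S ribosomal RNA locus, a block within low light only, a fit without nuclear ribosomal RNA loci and the lists without the 17 members were added after the data were seen. Exact matches of all 50-base windows of 186 named or called loci were counted over the TAIR10.1 genome, and loci with many second matches are given as uncertain. Permutations and splits of the libraries were run in R 4.3.3, the window matching in Python 3.11.15, and the exact counting intervals with scipy 1.17.1.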

Results

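The data were estimated RNA-seq counts from 12 libraries of whole 10-day seedlings, 3 for each of wild type and atrx-2 under normal and low light. ATRX is a chromatin remodeller that deposits the histone variant H3.3, and the series title places it with LHP1 at loci bound by the repressive complex PRC2. Totals were 17473391 to 23899191 estimated counts in the normal-light libraries and 13733302 to 21435587 in the low-light libraries. The first principal component held 54.9% of the variance and separated the light levels. The 18S ribosomal RNA locus AT3G41768 took 3.71% to 8.64% of counts under normal light and 9.77% to 16.7% under low light. Chloroplast genes took 2.29% to 3.55% and 4.83% to 8.90% respectively.

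ATRX (AT1G08600; chromosome 1, 2723677 to 2733613) was low in every atrx-2 library. Under normal light its counts were 753, 733 and 905 in wild type and 20, 18 and 16 in atrx-2. Under low light they were 681, 564 and 537 in wild type and 7, 6 and 15 in atrx-2. The mean fell from 38.1 ± 2.86 to 0.916 ± 0.109 CPM under normal light (SD, n = 3 each; 41.3-fold, adjusted p = 3.1e-11 by edgeR). Under low light it fell from 40.3 ± 4.60 to 0.505 ± 0.179 CPM (75.9-fold, adjusted p = 1.85e-11). LHP1 (AT5G17690), the reader of the PRC2 mark, was not called in any comparison, with means of 16.6 to 18.8 CPM.

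**Figure D1:**
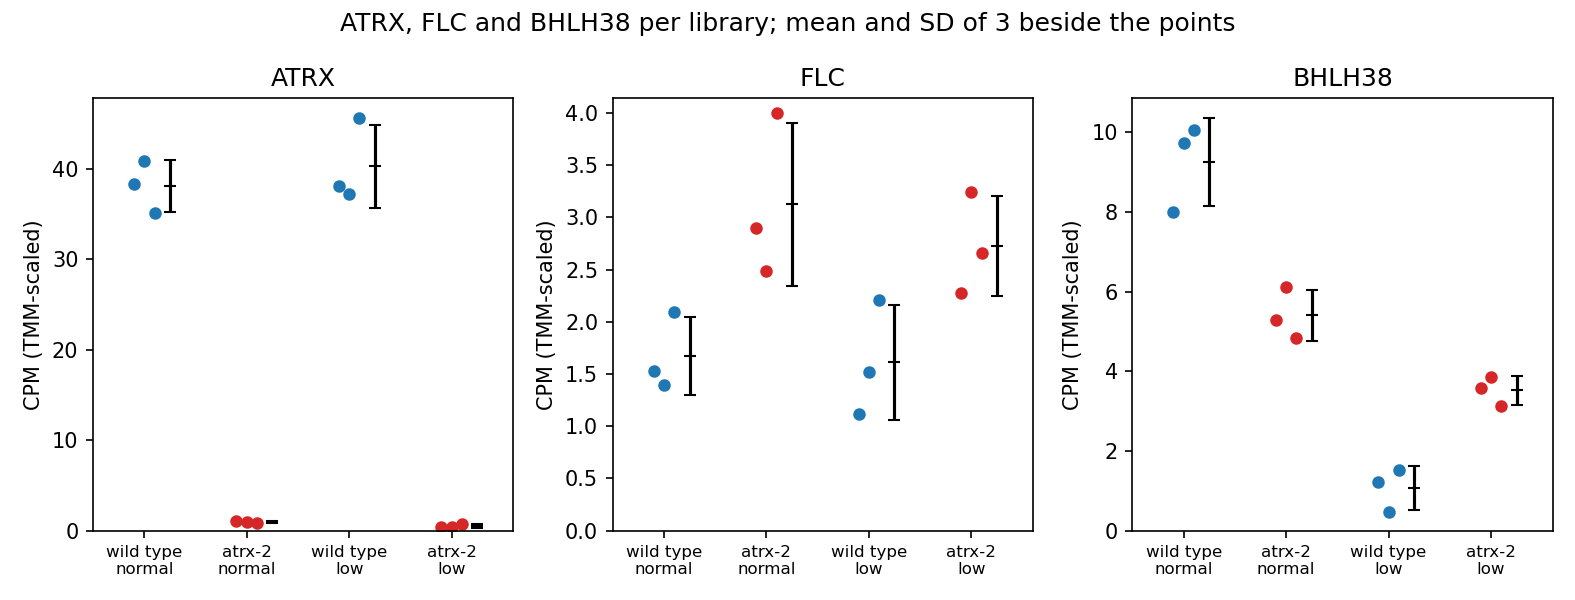
TMM-scaled CPM of ATRX, FLC and BHLH38 in each of the 12 libraries, by genotype and light level, with the mean and SD of 3 beside the points. ATRX lay near 40 CPM in wild type and near 1 CPM or below in atrx-2, FLC means were 1.67 and 1.61 CPM in wild type and 3.13 and 2.73 CPM in atrx-2, and BHLH38 was higher in wild type under normal light and higher in atrx-2 under low light.

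The comparison of atrx-2 with wild type under normal light asked whether loss of ATRX altered transcript levels. QQS (AT3G30720; chromosome 3, 12349047 to 12349933), an orphan gene that regulates carbon and nitrogen allocation, rose 6.26-fold, from 1.32 ± 0.306 to 8.18 ± 0.974 CPM (SD, n = 3 each; adjusted p = 0.000677). The oxidoreductase gene AT5G11330 (chromosome 5, 3617138 to 3618913) rose from 11.5 ± 1.56 to 35.5 ± 0.473 CPM (log2 1.62 ± 0.09 SE, adjusted p = 2.13e-07). Annotated pseudogenes AT1G25430 (10.2-fold) and AT3G13270 (3.02-fold) also rose, as did MORC6 (1.57-fold, adjusted p = 0.0232), an ATPase of gene silencing. SAG29, a senescence-associated sugar transporter gene, fell 2.17-fold from 22.7 ± 4.02 CPM, and NIC3, which encodes a nicotinamidase, fell 2.04-fold. The methyltransferase gene AT5G37990 fell 1.63-fold.

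In all, 14 of 20783 genes were called, 10 higher and 4 lower, while 1791 had an unadjusted p under 0.05. The remaining calls were AT3G60950, the methyltransferase gene AT4G33110 (1.76-fold), AT2G40520 (1.84-fold), PGL1 (1.74-fold) and the F-box gene AT3G44120 (2.04-fold), all higher. AT3G60950 held 2 counts over the wild-type libraries and 104 over atrx-2, a ratio of 55.8 (counting interval 15.1 to 467). It is uncertain, because 98.7% of its 50-base windows match a second place in the genome exactly. AT3G44120 is uncertain for the same reason, at 54.8%.

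Of the silencing list, 1 of 22 tested members rose under normal light, MORC6, and 2 when adjusted over the list alone; the list stood higher by camera (adjusted p = 0.0161; adjusted p = 0.598 with an estimated correlation). No member of the other 20 tested lists was called over all genes. Aliphatic glucosinolate genes, which make sulfur-rich defence compounds, had a median log2 of -0.22 over 13 members (adjusted p = 0.000188; adjusted p = 0.513 with an estimated correlation). Heat shock genes had a median of -0.26 over 14 members (adjusted p = 0.000875; adjusted p = 0.513 with an estimated correlation), with 1 lower when adjusted over the list alone. Antenna genes (-0.07; adjusted p = 0.0161) and cell cycle genes (-0.12; adjusted p = 0.0177) stood lower, with adjusted p = 0.598 and adjusted p = 0.73 with an estimated correlation. Salicylic acid genes (median 0.15; adjusted p = 0.0177) and low-sugar genes (0.09; adjusted p = 0.03) stood higher, with adjusted p = 0.513 and adjusted p = 0.598 with an estimated correlation. Adjusted over the list alone, 2 salicylic acid members were higher, and of the iron list 2 were higher and 1 lower. Median, mean and camera direction differed in sign for the flavonoid, high-light, chlorophyll, clock and cold lists.

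Calls of AT3G60950, SAG29, NIC3, AT5G37990 and MORC6 were lost in 7 of 15, 9 of 16, 7 of 15, 8 of 16 and 6 of 16 alternatives, whereas QQS and AT5G11330 stayed past the threshold in all 16. The count was 58 with DESeq2, 41 without the low-count filter and 22 without organelle genes. It was 7 with a filter of 5 CPM, 8 with only the 6 libraries, and 5, 7 and 9 without wild-type replicate 1, wild-type replicate 3 and atrx-2 replicate 1.

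Under low light the same question gave partly the same genes. QQS rose 8.80-fold, from 0.927 ± 0.629 to 8.63 ± 1.92 CPM (SD, n = 3 each; adjusted p = 0.000424), and AT5G11330 rose from 9.21 ± 0.216 to 29.6 ± 0.764 CPM (adjusted p = 3.14e-07). The noncoding RNA gene AT1G67105 (chromosome 1, 25057479 to 25058264) rose from 1.65 ± 0.519 to 5.90 ± 1.27 CPM, and BHLH38, a transcription factor gene of the iron deficiency response, rose from 1.07 ± 0.55 to 3.52 ± 0.36 CPM (adjusted p = 0.0237). The annotated pseudogene AT1G43590 (chromosome 1, 16414121 to 16414627) fell 8.27-fold from 4.74 ± 1.71 CPM, and the lipid transport gene AT1G14960 fell 2.99-fold. The AT14A pair (AT3G28290 and AT3G28300), whose products resemble integrin-like membrane proteins, fell 2.87-fold to 1.57 ± 0.288 CPM.

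In total 15 genes were called under low light, 9 higher and 6 lower, and 1359 had an unadjusted p under 0.05. The others were AT3G60170, AT3G60950, AT4G33110 (1.81-fold), AT2G40520 (2.33-fold) and AT3G13270 (2.83-fold), which were higher, and AT2G32870 (1.51-fold), which was lower, besides ATRX. AT3G60950 had no count in wild type and 181 in atrx-2, at least 50.6-fold higher. AT3G60170 (chromosome 3, 22232512 to 22236531) is an annotated pseudogene with no second copy of its windows. It had 1 count in wild type and 83 in atrx-2, a ratio of 69.7 (counting interval 12.2 to 2785). The AT14A loci are identical over 100% of windows and received equal counts, so they are 1 measurement, and AT1G43590 shares 11.6% of windows.

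The light-harvesting antenna list had a median log2 of -0.20 over 18 members under low light. It stood lower in atrx-2 by camera (adjusted p = 1.34e-16; adjusted p = 0.375 with an estimated correlation), with 0 members called over all genes and 9 lower when adjusted over the list alone. Glucosinolate genes had a median of -0.25 (adjusted p = 3.65e-06; adjusted p = 0.53 with an estimated correlation), with 0 called and 5 of 13 lower when adjusted over the list alone. Chlorophyll synthesis genes stood lower (median -0.10, adjusted p = 0.039; adjusted p = 0.53 with an estimated correlation), with 0 of 7 called and 1 lower when adjusted over the list alone. Iron genes stood higher (median 0.16, adjusted p = 0.00219; adjusted p = 0.375 with an estimated correlation), with BHLH38 as the only 1 of 15 called and 3 when adjusted over the list alone. In the other 17 tested lists no member was called, and adjusted over the list alone 2 cold genes and 1 root marker were lower. Median, mean and camera direction differed in sign for the damage response, shade, clock and root lists.

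BHLH38 lost its call under low light in 9 of 17 alternatives, AT1G14960 in 7 of 16 and AT3G60170 in 2 of 16, while QQS kept it in all 17. The count was 57 with DESeq2 (26 higher and 31 lower), 16 with a block within low light (7 and 9), 21 without wild-type low-light replicate 3 (9 and 12), 26 without the low-count filter, 9 with a filter of 5 CPM and 7 without wild-type low-light replicate 2.

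**Figure D2:**
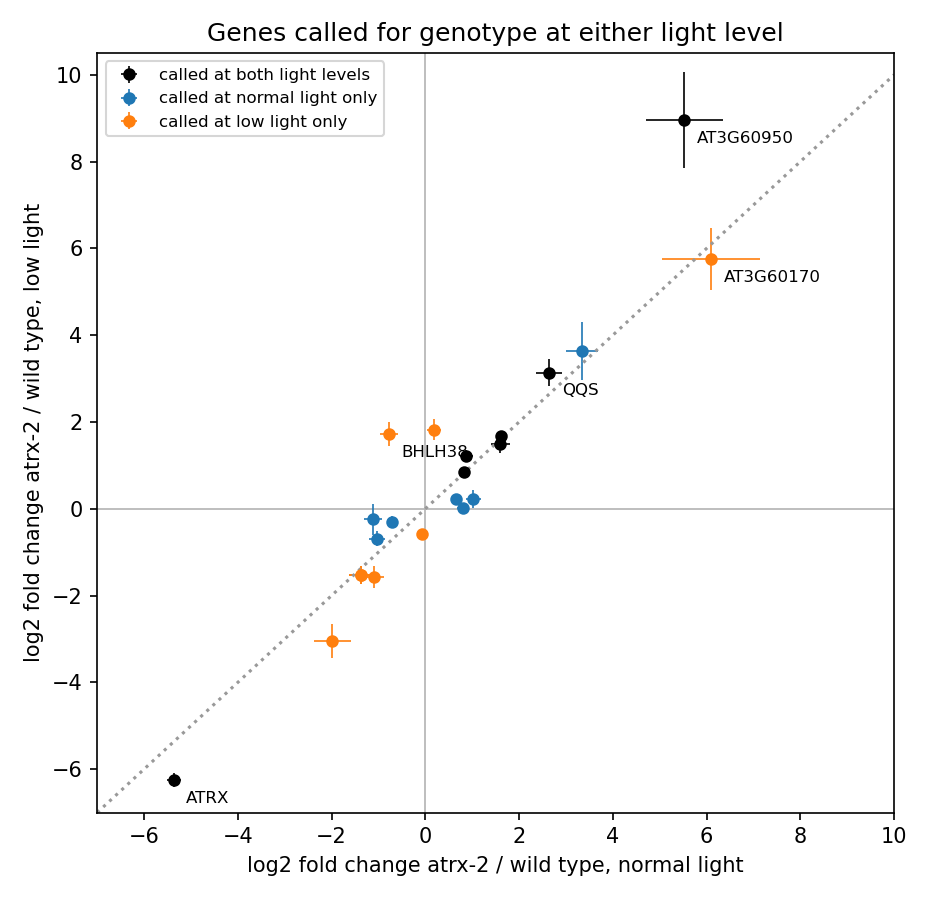
Fitted log2 fold changes of atrx-2 against wild type under normal light (x axis) and low light (y axis) for each gene called at either level, with bars of 1 standard error; the dotted line marks equal effects. Of the 21 genes other than ATRX, 20 had the same sign at both levels; fitted values of genes with almost no wild-type counts, such as AT3G60950 and AT3G60170, are no bounds.

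Averaging the genotype effect over both light levels gave the largest set of genotype calls among the 3 genotype contrasts. Besides ATRX, QQS (log2 2.89 ± 0.21 SE, adjusted p = 6.38e-06), AT5G11330, AT1G25430, AT3G60950 and AT3G60170 were higher, and AT1G43590, the AT14A pair and AT1G14960 (log2 -1.33 ± 0.17 SE) were lower. GRP19 (AT5G07550; chromosome 5, 2388225 to 2389249), a pollen coat glycine-rich oleosin gene, rose from 0.182 ± 0.085 to 1.07 ± 0.617 CPM under normal light and from 0.247 ± 0.154 to 1.13 ± 0.448 CPM under low light (adjusted p = 0.02 averaged). MORC6 rose (log2 0.44 ± 0.07 SE, adjusted p = 0.0122), as did the iron store gene FER1 (0.66 ± 0.12 SE, adjusted p = 0.0344). The cold-inducible gene KIN1 fell (log2 -1.25 ± 0.25 SE, adjusted p = 0.0485). In all 64 genes were called, 34 higher and 30 lower, with 2113 at an unadjusted p under 0.05. The split by direction was unstable, at 72 higher and 80 lower with DESeq2, 43 and 49 with the replicate block, 34 and 50 without atrx-2 normal-light replicate 1 and 35 and 15 without its replicate 2.

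FLC (AT5G10140; chromosome 5, 3173382 to 3179448), a floral repressor and PRC2 target, was higher in each atrx-2 library than in any wild-type library of the same light level, but was not called. Its averaged log2 was 0.84 ± 0.19 SE (adjusted p = 0.106 by edgeR), and it was the 1 gene higher in both the PRC2 target and flowering lists when adjusted over the list alone. Its means were 1.67 ± 0.373 and 3.13 ± 0.782 CPM in wild type and atrx-2 under normal light (adjusted p = 0.402), and 1.61 ± 0.55 and 2.73 ± 0.483 CPM under low light (adjusted p = 0.602). Over 20 alternatives its averaged adjusted p ran from 0.0296 to 0.289, and it passed the threshold in 2, DESeq2 and the 18S covariate. FLM, MAF2, MAF3, MAF4, MAF5 and FT had averaged log2 values of -0.04, 0.01, 0.04, 0.48, 0.08 and -0.34, with adjusted p from 0.621 to 0.975.

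No member of the PRC2 target list (17 tested), the Polycomb list (23), the histone chaperone list (15) or the flowering list (27) was called for genotype in any contrast. The PRC2 target list had an averaged median log2 of -0.02 and a mean of 0.02, and the signs of median, mean and camera direction also differed for the flowering and high-light lists. Averaged antenna genes stood lower (median -0.14, adjusted p = 6.03e-12; adjusted p = 0.658 with an estimated correlation), with 0 of 18 called over all genes and 10 lower when adjusted over the list alone. Glucosinolate genes had a median of -0.23 (adjusted p = 2.79e-08; adjusted p = 0.658 with an estimated correlation), with 0 of 13 called and 7 lower when adjusted over the list alone. Their regulator MYB29 had a log2 of -0.50 ± 0.10 SE (adjusted p = 0.0629) and the biosynthesis genes MAM1 and CYP79F1 had -0.27 and -0.39. Salicylic acid genes stood higher (0.16, adjusted p = 0.024), silencing genes stood higher (0.07, adjusted p = 0.0395) and cold genes lower (-0.21, adjusted p = 0.0479), each with adjusted p = 0.704 with an estimated correlation. Adjusted over the list alone, 2 salicylic acid genes, 1 silencing gene, 1 iron gene and 2 high-light genes were higher, and 2 cold genes and 1 high-light gene were lower; over all genes the called members were MORC6, FER1 and KIN1. KIN1, FER1 and GRP19 lost the averaged call in 11 of 21, 8 of 21 and 5 of 20 alternatives. The averaged count was 152 with DESeq2 and 100 without the low-count filter, and fell to 41, 42, 40, 33, 37 and 31 without wild-type normal-light replicates 1 and 3, wild-type low-light replicates 1 and 2, and atrx-2 low-light replicates 2 and 3.

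Across 20783 genes, which are not independent replicates, genotype effects at the 2 light levels had a Pearson r of 0.25 (0.24 without ATRX) and a Spearman rho of 0.17. No library was shared between them. ATRX, QQS, AT5G11330, AT4G33110, AT2G40520, AT3G13270 and AT3G60950 were the 7 genes called at both levels, against 0.0101 for independent lists. All 7 had the same sign. Both contrasts came from the same fit with a shared estimate of each gene's spread, so the expectation for independent lists is no test. The 7 also include ATRX, the mutated gene, and AT3G60950, which is uncertain.

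For low against normal light in wild type the antenna, heat shock, high-light, jasmonate, cell cycle, low-sugar and chlorophyll lists passed camera with the preset correlation. The chlorophyll list did not pass with the replicate block, and no list passed with an estimated correlation. Of all tested genes 34.2% were called in this comparison. Member counts near or under that share do not set a list apart. Of 18 antenna genes, which bind the light-harvesting chlorophylls, 16 rose and 1 fell under low light, beside an 18S share that reached 16.7% in a low-light wild-type library and at most 6.84% under normal light. LHCB1.4 rose from 500 ± 46.1 to 3793 ± 106 CPM (log2 2.92 ± 0.09 SE, adjusted p = 6.06e-11), and LHCB4.3 fell from 52.1 ± 5.22 to 10.3 ± 2.56 CPM. LHCB1.3 and LHCB1.2 rose to 15867 ± 392 and 6938 ± 497 CPM; LHCB1.3 and LHCB1.2 share 17% and 10.7% of windows with other places in the genome and LHCB1.4 shares a similar part, so their separate values are uncertain. The antenna list stood higher (adjusted p = 3e-11; adjusted p = 0.488 with an estimated correlation), with 17 higher and 1 lower when adjusted over the list alone.

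Of 7 chlorophyll synthesis genes 4 rose and 1 fell in wild type, with the same counts adjusted over the list alone. The protochlorophyllide reductase genes PORA and PORB rose from 0.272 ± 0.0368 to 4.67 ± 0.201 CPM and from 47.6 ± 10.3 to 457 ± 45.4 CPM (SD, n = 3 each; adjusted p = 1.58e-07 and 3.07e-08), and CAO and HEMA1 rose by log2 0.42 and 0.29. The list stood higher (adjusted p = 0.0444; adjusted p = 0.56 with an estimated correlation). This list call was lost with the replicate number as a block (adjusted p = 0.0557). Chloroplast transcripts took 4.83% to 8.90% of wild-type low-light counts against 3.36% to 3.43%.

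Of 14 heat shock genes 11 fell under low light and 1 rose (11 and 2 adjusted over the list alone). HSP17.6II fell from 42.4 ± 13.1 to 0.294 ± 0.192 CPM, HSP17.4 from 39.5 ± 4.85 to 0.575 ± 0.207 CPM (log2 -6.02 ± 0.21 SE, adjusted p = 1.05e-10) and HSP17.6A from 10.3 ± 2.08 to 0.128 ± 0.0416 CPM; these encode small chaperones. HSP23.6 had 106 counts under normal light and 2 under low light, a ratio of 37.5 (counting interval 10.1 to 314). The small chaperone gene AT1G53540 fell from 21.3 ± 2.4 to 0.222 ± 0.0791 CPM, and AT3G29970, a B12D protein gene outside the list, had 637 and 3 counts, a ratio of 150 (51.2 to 731). The list stood lower (adjusted p = 2.69e-06; adjusted p = 0.488 with an estimated correlation), in libraries whose 18S share was higher under low light.

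High-light response genes fell in 8 of 15 cases and rose in 1 (9 and 2 adjusted over the list alone; adjusted p = 0.00144, and adjusted p = 0.56 with an estimated correlation). The peroxidase gene GPX7 fell from 15.3 ± 1.95 to 2.54 ± 0.45 CPM, the ascorbate synthesis gene VTC2 from 489 ± 128 to 140 ± 6.97 CPM and the early light-inducible gene ELIP1 from 17.3 ± 4.66 to 5.23 ± 1.23 CPM. APX2 had 46 counts under normal light and 3 under low light, a ratio of 10.9 (3.49 to 54.6). Jasmonate genes fell in 9 of 17 cases, also 9 adjusted over the list alone (adjusted p = 0.0161, and adjusted p = 0.669 with an estimated correlation). They included VSP2, which fell from 24.9 ± 8.45 to 3.51 ± 0.937 CPM, and JAZ7, JMT and JAZ5, with log2 values of -3.55, -3.27 and -2.96. Flavonoid genes fell in 7 of 16 cases and rose in 1, also 7 and 1 adjusted over the list alone (adjusted p = 0.0609). Chalcone synthase TT4 fell from 424 ± 39 to 133 ± 22.8 CPM and F3H and MYB111 by log2 -1.61 and -1.60, whereas the repressor MYBL2 rose from 27.7 ± 3.97 to 90.3 ± 0.0842 CPM.

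Cell cycle genes rose in 6 of 23 cases and fell in 1, also adjusted over the list alone (adjusted p = 0.0161, and adjusted p = 0.774 with an estimated correlation); they included MCM4 (log2 0.66), MCM6, MCM7 and the histone gene HTR3. Low-sugar genes rose in 6 of 14 cases and fell in 1, with 9 and 1 adjusted over the list alone (adjusted p = 0.0161, and adjusted p = 0.669 with an estimated correlation). TPS10, DRM1 and KMD4 rose by log2 0.99, 0.81 and 0.62, and DIN9 fell (-1.24). Of 24 clock genes 10 rose and 10 fell, also 10 and 10 adjusted over the list alone, and the list did not stand apart (adjusted p = 0.77; median 0.08, mean -0.01). The morning gene LHY fell from 271 ± 23.3 to 50.2 ± 3.07 CPM and RVE1 4.45-fold from 89.1 ± 9.74 CPM, while PRR5 rose from 0.83 ± 0.373 to 4.07 ± 1.03 CPM and FKF1 from 0.124 ± 0.0639 to 0.964 ± 0.049 CPM.

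The root markers only rose in wild type, the other lists changed in both directions, and none of these passed its list test. The counts in this and the next paragraph are to be read beside the 34.2% of all tested genes called. Shade genes rose in 4 of 18 cases and fell in 7, also adjusted over the list alone, with IAA29 at log2 2.09 and HFR1, PIL1 and YUC2 at -1.49, -1.45 and -1.28. Iron genes rose in 3 of 15 cases and fell in 8 (4 and 8 adjusted over the list alone), with BHLH38, BHLH100, BHLH39 and BHLH101 at -3.13, -2.38, -1.63 and -1.11. Flowering genes rose in 9 of 27 cases and fell in 5 (9 and 6 adjusted over the list alone); FLM and MAF3 rose by log2 0.60 and 0.62, MAF2 rose by 0.52, AGL24, SPL5, CO and FT fell (-1.57, -1.98, -1.49 and -1.56), and FLC had -0.11 (adjusted p = 0.804). Of 17 PRC2 targets 2 rose and 6 fell, also adjusted over the list alone, with DOG1 going from 0.119 ± 0.144 to 2.84 ± 0.412 CPM and AGL19 and PI at log2 -2.30 and -1.58.

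Polycomb genes rose in 5 of 23 cases (CLF 0.46, ATX1 0.58 and RING1A 0.55 among them) and fell in 2 (BMI1B -0.59), with the same counts adjusted over the list alone. Histone chaperone genes rose in 3 of 15 cases (FAS1 0.55, FAS2 0.64, CABIN1 0.37) and fell in 3 (NRP1 -0.59), with 4 and 4 adjusted over the list alone. Silencing genes rose in 6 of 22 cases and fell in 1, with MET1 at 0.55, DME at 0.53, DDM1 at 0.49 and ROS1 at -0.45, and damage response genes rose in 2 of 18 (RAD54 0.86, RAD17 0.74) and fell in 1 (SMR5 -1.60), both also adjusted over the list alone. Salicylic acid genes rose in 5 of 15 cases and fell in 3 (6 and 3 adjusted over the list alone), with ACD6 at -1.72, PBS3 at -1.49, WRKY70 at -1.29 and SAG101 at 0.85. Cold genes rose in 2 of 14 cases and fell in 3, with GOLS2 at -3.35, LTI30 at 1.07, KIN2 at -0.79 and P5CS1 at -0.77, and glucosinolate genes rose in 3 of 13 and fell in 3, with MAM1 at 0.86, CYP79F1 at 0.56, UGT74C1 at -0.50 and FMOGS-OX1 at -0.58, both also adjusted over the list alone. Root markers rose in 3 of 20 cases (NRT2.1 1.57, WER 0.89, TIP2;3 0.85; 2 adjusted over the list alone). Median, mean and camera direction differed in sign for the flowering, Polycomb, salicylic acid, clock, glucosinolate and root lists in wild type.

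Over all genes 7113 differed with light in wild type, 3449 higher and 3664 lower under low light, and 9112 had an unadjusted p under 0.05. Among the largest rises the defensin gene PDF1.3 went from 0.12 ± 0.0703 to 3.44 ± 3.66 CPM and AT4G22470 from 0.409 ± 0.176 to 11.2 ± 5.92 CPM; LpxC1 went from 0.0558 ± 0.0584 to 10.3 ± 6.23 CPM but is uncertain, since 100% of its windows have a second copy. With the 18S share as a covariate the count was 2548, and 38 of 94 named-gene values in this comparison lost their call. Over all alternatives the calls of CO and BHLH101 were lost in 7 of 15 each, those of FT, PIL1 and WER in 5 of 15 each, and those of HEMA1 and FMOGS-OX1 in 5 of 16 each. With an added log2 threshold of 1 it was 1502, of which 611 were higher.

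**Figure D3:**
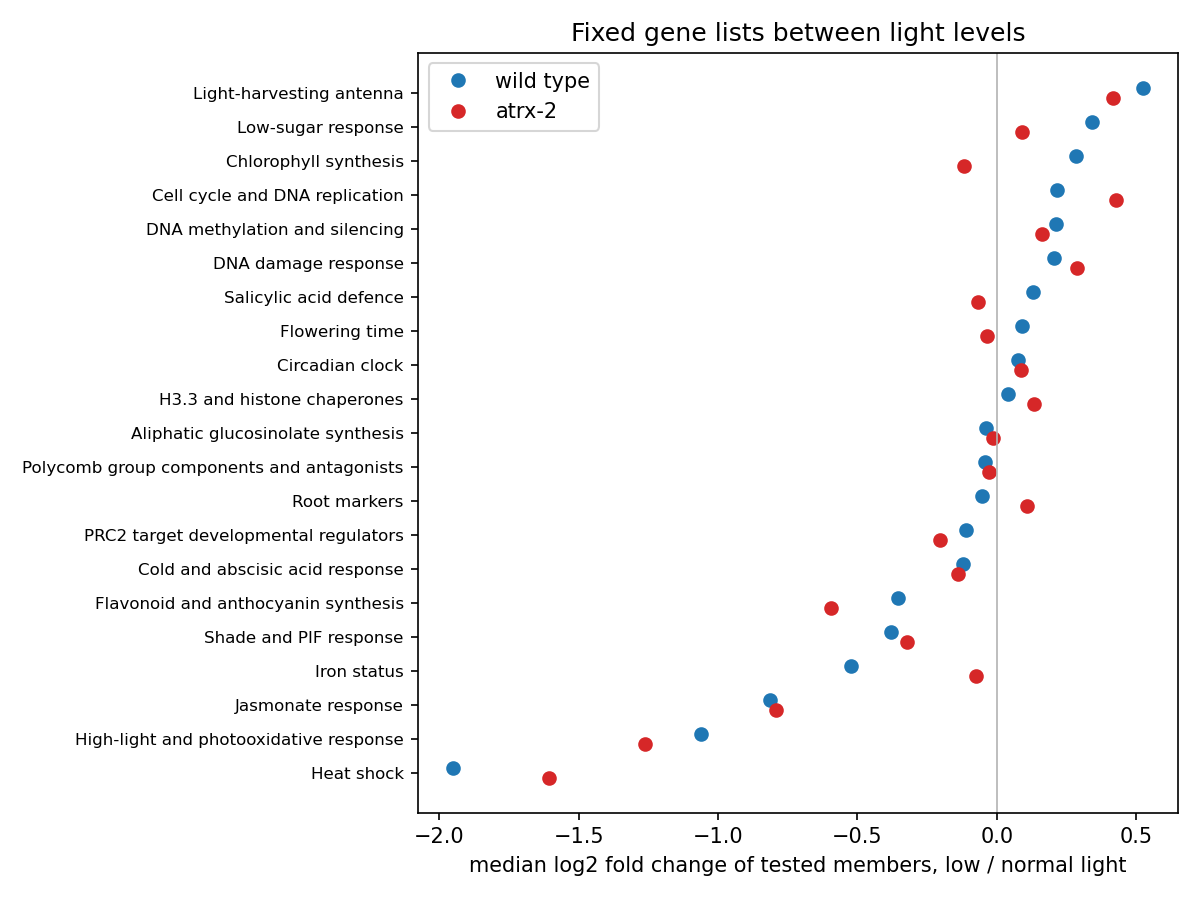
Median log2 fold change of low against normal light over the tested members of each fixed list, in wild type (blue) and atrx-2 (red); each point is 1 list, without error bars. Heat shock, high-light and jasmonate medians lay lowest in both genotypes (-1.95 and -1.61, -1.06 and -1.26, -0.82 and -0.79 in wild type and atrx-2), and the antenna medians were 0.53 and 0.42.

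Low against normal light in atrx-2 changed many of these groups again. Of all tested genes 33.1% were called in this comparison, and member counts near or under that share do not set a list apart. Of 18 antenna genes 16 rose and 1 fell, also adjusted over the list alone (LHCB1.4 from 503 ± 14.5 to 3049 ± 309 CPM; list adjusted p = 1.48e-08, and adjusted p = 0.53 with an estimated correlation). Of 14 heat shock genes 11 fell and 2 rose, also adjusted over the list alone (adjusted p = 1.03e-05, and adjusted p = 0.53 with an estimated correlation), with HSP17.6II going from 27.2 ± 2.43 to 0.156 ± 0.12 CPM and HSP23.6 at least 18.7-fold lower, from 62 counts to 0. High-light genes fell in 9 of 15 cases and rose in 1, with 10 and 1 adjusted over the list alone (adjusted p = 0.000133, and adjusted p = 0.53 with an estimated correlation); VTC2 fell from 477 ± 111 to 127 ± 15.2 CPM, and GPX7 and SIG5 by log2 -2.76 and -1.48. APX2 had 31 counts and 2 counts, a ratio of 14.0 (3.57 to 121).

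Cell cycle genes rose in 15 of 23 cases in atrx-2 and fell in 0, with 15 and 1 adjusted over the list alone (adjusted p = 0.000133, and adjusted p = 0.813 with an estimated correlation); MCM4, CDKB1;1, HTR2 and MCM6 rose by log2 0.68, 0.68, 0.56 and 0.55. Flavonoid genes fell in 8 of 16 cases and rose in 1, also adjusted over the list alone (adjusted p = 0.0177, and adjusted p = 0.53 with an estimated correlation), with TT4 at -1.47, F3H at -1.29, MYB12 at -1.26 and MYBL2 at 1.27. Jasmonate genes fell in 10 of 17 cases and rose in 1, with 11 and 1 adjusted over the list alone (adjusted p = 0.0104, and adjusted p = 0.791 with an estimated correlation), including VSP2 (-3.15), JAZ7 (-3.83), JMT and JAZ5. The 18S and chloroplast shares differed between light levels in atrx-2 as well, at 3.71% to 8.64% against 9.77% to 15.4% and 2.29% to 3.55% against 4.91% to 7.12%.

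Chlorophyll genes rose in 3 of 7 cases in atrx-2 and fell in 1 (3 and 2 adjusted over the list alone), with PORA at log2 4.41, PORB at 3.32, CAO at 0.27 and GUN4 at -0.25; the list had a median of -0.12 and a mean of 1.04. Clock genes rose in 9 of 24 cases and fell in 10 (11 and 11 adjusted over the list alone), with LHY at -2.58, RVE1 at -2.03, PRR5 at 2.67 and FKF1 at 2.73. Low-sugar genes rose in 5 of 14 cases and fell in 2 (6 and 3 adjusted over the list alone), with TPS10 at 0.97, DRM1 at 0.92, DIN9 at -1.52 and ASN1 at -0.94. Shade genes rose in 3 of 18 and fell in 6 (3 and 7 adjusted over the list alone), with IAA29 at 1.96, XTH15 at 0.93, HFR1 at -1.48 and PAR2 at -1.06. Flowering genes rose in 7 of 27 cases and fell in 3, also adjusted over the list alone; FLM, MAF3, GI and SOC1 rose by 0.48, 0.38, 1.28 and 0.71, AGL24 and FT fell (-2.07 and -2.28), and MAF2 (0.22, adjusted p = 0.131) and FLC (-0.21, adjusted p = 0.571) were not called. Median, mean and camera direction differed in sign for the chlorophyll, flowering, clock, damage response, salicylic acid, glucosinolate and iron lists in atrx-2.

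PRC2 targets rose in 2 of 17 cases in atrx-2 and fell in 6, with DOG1 at 3.23, SEP1 at -3.11 and AGL19 at -2.29, and silencing genes rose in 4 of 22 and fell in 2, with MET1 at 0.53, DME at 0.40, NRPE1 at 0.37 and ROS1 at -0.66, both also adjusted over the list alone. Polycomb genes rose in 4 of 23 cases and fell in 5 (5 and 6 adjusted over the list alone), with RING1A at 0.62, ATX1 at 0.47, BMI1B at -0.53 and RING1B at -0.43. Histone chaperone genes rose in 5 of 15 cases, including FAS1, FAS2 and ASF1B (0.61, 0.61 and 0.46), and fell in 1, NRP1 (-0.38), also adjusted over the list alone. Damage response genes rose in 3 of 18 cases and fell in 2 (5 and 2 adjusted over the list alone), with RAD54 at 0.58, WEE1 at 0.57, SMR5 at -2.97 and NAC044 at -1.53. Salicylic acid genes rose in 4 of 15 and fell in 3 (5 and 3 adjusted over the list alone), with PR5 at 0.93, WRKY70 at -1.32, ACD6 at -1.24 and PBS3 at -1.17. Cold genes rose in 1 of 14 cases and fell in 5, with GOLS2 at -3.04, KIN1 at -1.08, KIN2 at -1.03 and LTI30 at 1.28, and glucosinolate genes rose in 3 of 13 and fell in 2, with MAM1 at 0.57, CYP79F1 at 0.42, UGT74C1 at -0.41 and MYB29 at -0.73. Iron genes rose in 3 of 15 and fell in 2, with FER1 at 0.63, FIT at 0.47, BHLH38 at -0.63 and NAS4 at -0.48, and root markers rose in 3 of 20, with TIP2;3 at 1.15, WER at 1.02 and PRP1 at 0.86. The cold, glucosinolate, iron and root counts were the same adjusted over the list alone, and none of the lists in this paragraph passed its list test.

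In atrx-2 6870 genes differed with light, 3353 higher and 3517 lower, with 8831 at an unadjusted p under 0.05. Among those with the largest changes, the peroxidase gene AT1G49570 had 0 counts under normal light and 133 under low light, at least 49-fold higher, AT2G30362 was at least 23.2-fold higher (14.3 without atrx-2 low-light replicate 1, and a call lost in 9 of 15 alternatives), and AT1G29090 went from 1 count to 78, a ratio of 86.2 (15 to 3447). AT5G15500 was at least 38.9-fold lower and AT3G22275 at least 21.1-fold lower under low light. The bound for AT3G22275 was 8.15 without atrx-2 normal-light replicate 1, and its call was lost in 1 of 14 alternatives, the 18S covariate. AT4G19430 went from 460 counts to 1, a ratio of 416 (74.4 to 16480). PDF1.3 went from 0.187 ± 0.155 to 6.77 ± 2.01 CPM. With the 18S share as a covariate the count was 2902, and 37 of 97 named-gene values lost their call; with an added log2 threshold of 1 it was 1477, of which 577 were higher. The remaining ATRX transcript was lower under low light in atrx-2 (log2 -0.80, adjusted p = 0.0452), a call lost in 10 of 16 alternatives. In this comparison calls were also lost for WEE1 in 7 of 15, FAS2 in 6 of 15, KIN1, MAF3 and FIT in 6 of 16 each, NAC044 in 5 of 15, and NAS4 and NRPE1 in 5 of 16 each.

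Light effects in the 2 genotypes had a Pearson r of 0.82 and a Spearman rho of 0.81 across genes. Of the genes called in either genotype 5182 were called in both, against 2350 for independent lists, and 5179 of these had the same sign. Here too the same fit and estimate of spread served both contrasts, so the lists are not independent. PORA, PORB, LHCB1.4, HSP17.6II and LHY were among the named genes called in both.

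The interaction asked whether the genotype effect differed with light, and 1 gene was called. BHLH38 (AT3G56970; chromosome 3, 21084035 to 21085245) was at 9.26 ± 1.11 CPM in wild type and 5.41 ± 0.642 CPM in atrx-2 under normal light, and at 1.07 ± 0.55 and 3.52 ± 0.36 CPM under low light (log2 2.51 ± 0.33 SE, adjusted p = 0.0461). The iron list stood higher in the interaction (median 0.24, adjusted p = 0.000574; adjusted p = 0.424 with an estimated correlation), with 1 of 15 members called and 3 adjusted over the list alone. Antenna genes (-0.12, adjusted p = 0.000254) and low-sugar genes (-0.28, adjusted p = 0.00133) stood lower, each with adjusted p = 0.549 with an estimated correlation, and cell cycle genes stood higher (0.12, adjusted p = 0.0153; adjusted p = 0.787 with an estimated correlation), with 0 members called in these 3 lists, also adjusted over the list alone. In the other 17 tested lists 0 members were called, and 1 chlorophyll gene was lower adjusted over the list alone. Median, mean and camera direction differed in sign for the damage response, flavonoid, shade and jasmonate lists. FLC had an interaction log2 of -0.09 ± 0.39 SE (adjusted p = 0.992). The BHLH38 interaction was lost in 13 of 21 alternatives, with adjusted p from 7.73e-08 to 0.249, and 915 genes had an unadjusted p under 0.05.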

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

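The alternatives with the 18S share as a covariate and without ribosomal RNA loci were chosen after the data were seen; the other tests of this part were fixed beforehand. The results listed here are those in which the genotype effect differed between light levels by the test of the interaction.

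BHLH38 had an interaction log2 of 2.51 (adjusted p = 0.0461 by edgeR), the 1 call of that test. In wild type BHLH38, BHLH100, BHLH39 and BHLH101 fell with low light, and in atrx-2 BHLH38 fell by 0.63 on the log2 scale. Of 100 splits of the libraries within light level, 9 gave at least 1 interaction call, the real split included, so chance is not excluded. The highest of the other splits called 42 genes and the next called 15. A split with that many calls points to a structure among the libraries, which was not tested further: it set wild-type replicates 1 and 2 and atrx-2 replicate 1 apart under normal light, and wild-type replicate 3 and atrx-2 replicates 2 and 3 apart under low light. The BHLH38 call was absent without wild-type normal-light replicate 1, 2 or 3, or atrx-2 normal-light replicate 2 or 3, each left out singly. It was also absent without wild-type low-light replicate 1 or atrx-2 low-light replicate 1, 2 or 3, so it rests on most single libraries.

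By the same test of the difference, the iron list stood higher in the interaction (adjusted p = 0.000574) and the cell cycle list also stood higher (adjusted p = 0.0153). The antenna list (adjusted p = 0.000254) and the low-sugar list (adjusted p = 0.00133) stood lower. With an estimated correlation the adjusted p of these 4 lists was 0.424, 0.787, 0.549 and 0.549.

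For the averaged genotype comparison 100 of the 200 possible splits within light level were drawn. Of these 1, the real one, gave as many as 64 calls and the highest other gave 6, so the libraries grouped by genotype label. Mixed splits hold genotype differences in their spread, which can lower their calls. A difference between cultures unrelated to the mutation would pass this test too, so it does not exclude one. The remaining comparisons allow only 10 splits, too few for a share under 0.05. Their real counts and highest others were 14 and 4 for genotype under normal light, 15 and 7 under low light, 7113 and 0 for light in wild type, and 6870 and 0 for light in atrx-2; in each, 1 split, the real one, gave as many calls. No test of outlying samples was made in groups of 3 libraries; on the second principal component atrx-2 normal-light replicate 1 lay at -32.7, against 3.92 and -4.64 for replicates 2 and 3.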

How the results depend on the processing

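Tests chosen after the data were seen are the 18S covariate, the fit without ribosomal RNA loci, the block within low light, the lists without 17 members and the check of the numbers at log2 CPM above 2. No named gene that was called changed direction under an alternative, and no scaling moved the median of all genes by over 0.1. Of 4208 values of named genes under alternatives 3908 stayed on the same side of the threshold, 297 lost a call and 3 gained it; 79 of the losses came with the 18S covariate and 177 with libraries left out. Some values that were not called changed sign, such as FT under normal light (log2 -0.62 to 0.37) and FLM (-0.04 to 0.11).

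The balance of higher and lower genotype calls turned under several alternatives. Under low light 9 higher and 6 lower became 26 and 31 with DESeq2, 7 and 9 with a block within low light and 9 and 12 without wild-type low-light replicate 3. Averaged, 34 and 30 became 72 and 80 with DESeq2, 43 and 49 with the replicate block, 34 and 50 without atrx-2 normal-light replicate 1, 35 and 38 without atrx-2 low-light replicate 1 and 33 and 40 without wild-type low-light replicate 3; without atrx-2 normal-light replicate 2 they became 35 and 15. Under normal light 10 and 4 became 5 and 4 without atrx-2 replicate 1 and 16 and 1 without its replicate 2, so no direction is claimed to prevail for genotype.

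With DESeq2 the calls were 58 for genotype under normal light, 57 under low light, 152 averaged and 3 for the interaction; all calls of the edgeR fits (14, 15, 64 and 1) were among them. Without a low-count filter they were 41, 26 and 100 for the first 3. A filter of 5 CPM, which tests fewer genes, gave 7, 9 and, for the interaction, 0. Fits of only 6 libraries gave 8 under normal light, and leaving out organelle genes gave 22. The log2 threshold of 1, stricter by construction, gave 9 under normal light, 25 averaged, 1502 for light in wild type and 1477 in atrx-2. The 18S covariate gave 2548 and 2902 for light in the 2 genotypes and 0 for the interaction, and limma-voom gave 0 for the interaction. List calls numbered 33, with 0 with an estimated correlation. The fry test, which asks whether a list moves one way and not whether it stands apart from other genes, gave 20, of which 12 were among the 33. All 20 were in the light comparisons, and its lowest adjusted p was 0.42 for genotype under normal light, 0.102 under low light, 0.117 averaged and 0.371 for the interaction. With a filter of 5 CPM the concordance r was 0.30 for genotype effects and 0.92 for light effects. Apart from the construction named, the cause was not tested.

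Without single libraries the calls ran from 5 to 17 for genotype under normal light, 7 to 21 under low light, 31 to 84 averaged, 5697 to 6736 for light in wild type, 5398 to 6129 in atrx-2, and 0 to 2 for the interaction. Concordance r ran from 0.18 to 0.24 for genotype effects and 0.76 to 0.79 for light effects. Counts moved by over 1.5 times without wild-type normal-light replicates 1 and 3 and atrx-2 normal-light replicate 1 (5, 7 and 9), and without wild-type low-light replicate 2 (7). For the averaged comparison this held without wild-type normal-light replicates 1 and 3, wild-type low-light replicates 1 and 2 and atrx-2 low-light replicates 2 and 3 (41, 42, 40, 33, 37 and 31). The interaction had 2 calls without atrx-2 normal-light replicate 1 and 0 without wild-type normal-light replicates 1, 2 and 3, atrx-2 normal-light replicate 2 and atrx-2 low-light replicates 1 and 2.

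The replicate numbers were treated as shared numbers only: over all tested genes the correlation of same-numbered deviations was not over 0.1 for every pair in any pair of groups (0.096, 0.094 and 0.145 between genotypes under low light). At log2 CPM above 2 those values were 0.175, 0.125 and 0.226, each over 0.1, so a pairing of the low-light libraries is left open. Over all tested genes every library correlated best with its own number between genotypes under low light and between light levels in wild type, a hint from the data and not the design. The replicate block gave 11, 17, 92, 7540, 7234 and 0 calls in the 6 comparisons, in the order genotype under normal light, low light and averaged, light in wild type and atrx-2, and interaction; a block within low light gave 16 (7 higher and 9 lower), of which 13 were among the 15 called without it. The replicate block gave 32 list calls, without the chlorophyll list for light in wild type (adjusted p = 0.0557), and changed no other count by over 1.5 times than that of the interaction.

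Small effects were often missed: in simulated data with 3 libraries per group 22% of 1.5-fold interaction effects were recovered. For genotype under normal and low light the shares were 47% and 50%. The interaction combines the spread of all 4 groups, which widens its error by design. A group at 0 counts allows 0.0473 to 0.0669 CPM.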

Other observations

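Tests chosen after the result was seen are the over-representation, repeat and chromosome-block tests of the pseudogenes, the count of loci without a second match, the clock-phase test with its assignment of genes to phases, the bootstrap rule of the copy test, both single-library tests of the heat shock genes, and the rule that reads the covariate tests.

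Some averaged genotype calls were close neighbours, which was noticed in the data, and no test of clustering was made. On chromosome 5 GRP19, GRP20 and AT5G07570, glycine-rich oleosin-like genes, had log2 values of 2.31, 1.45 and 0.77 in atrx-2, while on chromosome 2 the neighbours AT2G32150 and AT2G32160 went opposite ways (-0.41 and 0.70). On chromosome 3 AT3G60930, AT3G60950 and, further off, AT3G61030 had positive values, with 25.2%, 98.7% and 98.5% of windows shared with other loci, so how many of them changed is uncertain. The annotated pseudogene AT3G60170 also rose in that region, starting at 22232512 against 22514027 for AT3G60930, and its windows had no second match. SARD1, a regulator of salicylic acid synthesis, had 1.48 ± 0.36 SE (adjusted p = 0.13) and was not called.

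Annotated pseudogenes made up 8 of the 64 averaged genotype calls and 286 of 20783 tested genes, or 12.5% against 1.38% (3 of 44 with a filter of 5 CPM). A two-sided Fisher's exact test gave p = 2.65e-06, but the class was picked after the calls were seen, so this p does not exclude chance. AT1G25430, AT3G13270, AT3G60170, AT3G60930, AT3G30122, AT5G28335 and AT2G15810 were higher in atrx-2 and AT1G43590 was lower. The class was every locus whose annotated biotype contains the word pseudogene, and it rests on that label alone. What kind of locus each one is was not examined, so transposable elements among them are not excluded. At the 4 loci called within a light level, calls from low counts that do not repeat are argued against. Of these 4, each counted once, 4 moved the same way with unadjusted p under 0.05 at the other level, including AT3G13270, which was called at both. The other 4 were called only in the average, and 3 of them had unadjusted p under 0.05 at both levels, with AT2G15810 under low light the exception. For these 4 low counts cannot be told apart from a change, since they were picked on the average of both levels. A chromosome block around ATRX, carried along with the mutation, is argued against for the class as a set, since 0 of 8 lay within 5 Mb of ATRX and 6 lay on other chromosomes. AT1G25430 and AT1G43590 lay on chromosome 1, starting at 8927732 and 16414121, against 2723677 for ATRX. A block longer than the bound was not tested, so a linked difference is not excluded for AT1G25430 and AT1G43590. Segments carried elsewhere in the genome were not tested, and AT3G60170 and AT3G60930 lay near each other on chromosome 3. Of the 63 averaged calls other than ATRX 4 lay within 5 Mb of ATRX, an interval which holds 1826 of 20782 tested genes: CCS, AT1G14730, AT1G14960 and MORC6. A linked difference was not excluded for them. At 3 loci, AT1G25430, AT3G13270 and AT3G60170, no window had a second exact match, so no exact copy in the reference genome could share their reads. Copies that differ within each window were not searched, so reads shared with such copies are left open. For the class as a set shared reads cannot be told apart from a change, since the shares ran up to 63.6%, with a median of 5.14% and a bootstrap interval of 0% to 25.2%. A hypothesis that remains open is that loss of ATRX may raise transcripts from some loci with a pseudogene biotype, of whatever kind. A second allele or a complemented line, absent here, would test this hypothesis.

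Evening clock genes exceeded morning ones under low light by a median log2 of 1.16 in wild type (12 against 11 genes) and 1.64 in atrx-2. A shift in clock phase or in the time of sampling would give this, but the genes were assigned to phases after part of the values were seen, so the difference does not test it. In wild type the ribosomal RNA share as the whole cause cannot be decided. With it as a covariate 98.7% of the median change of the 20 genes called there was left (bootstrap interval over genes 66% to 136%). A call was kept by 14 of 20, as the median SE went from 0.106 to 0.162. The rule settled after the values were seen reads an interval wholly above 50% as against the share, though it reaches below the 80% bound set in advance. The share was higher in every low-light library than in any normal-light one, so the covariate was fitted only from scatter within groups. The interval resampled genes with that fit held fixed, so it leaves out the spread between libraries. Sampling time, which the labels do not give, and a phase shift with light may both apply and were not separated.

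Among 14 heat shock genes 11 were lower and 1 was higher under low light in wild type, and 11 and 2 in atrx-2. The labels give the same temperature for both light levels. By camera with an estimated correlation the list call was lost in both genotypes (adjusted p = 0.488 and adjusted p = 0.53). The ribosomal RNA share as the whole cause cannot be decided in wild type, for the same reasons as for the clock genes. Under the covariate 93.2% of the median change of the 11 fallen genes was left (interval 75.8% to 98.4%). A call was kept by 7 of 11, as the median SE went from 0.217 to 0.32. In 7 of 11 the lowest normal-light wild-type library was at least 2 times the highest low-light library, which leaves a single warm library open, but without any wild-type normal-light library in turn at least 10 of 11 stayed called, which argues against it in wild type. For atrx-2 these tests were not made for the clock or heat shock genes as sets. Its named genes of all lists were refitted singly. Of their values 37 of 97 lost a call under the covariate and 69 of 582 with a library left out. Warmer tissue in all normal-light libraries may contribute and was not tested, as the design offers no temperature contrast.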
